A study of Mus musculus with 12 samples.

How the data were processed

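RNA was measured in B cells from the spleens of C57BL/6 mice with a green fluorescent protein reporter in the Prdm1 gene, which encodes the transcription factor Blimp1. Cells enriched by B220 beads were cultured for 4 days with 25 µg/ml lipopolysaccharide (LPS) and sorted into 3 populations. Activated B cells (ActB) were negative for CD138 and for the reporter, pre-plasmablasts (PrePB) were negative for CD138 and positive for the reporter, and plasmablasts (PB) were positive for both. The mice were wild type (wt) or lacked Mzb1 (ko). Each of the 6 groups held 2 libraries, 12 in all. Per the labels, RNA came from RNeasy columns, polyadenylated RNA was selected with oligo-dT, and libraries were made with a stranded TruSeq mRNA kit.

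The deposited values are FPKM, fragments scaled to transcript length and library size, with 1 file per library and 24325 gene symbols in each. The processing notes of the authors name bcl2fastq 0.3.1 and 2.17.1.14, TopHat2 2.0.14, Cufflinks 2.2.1, Cuffdiff without a version, Cuffnorm 2.2.1 and the mm9 mouse genome build. They do not state the gene annotation, the library scaling or any filter. The files hold no counts and no coordinates, so absolute sequencing depth is unknown, no counting interval was computed and genes are given by symbol only. No constant-region immunoglobulin gene is among the symbols (0 listed), so immunoglobulin transcripts were not analysed here.

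The values were analysed as log2(FPKM + 1), with no further scaling. Genes with at least 1 FPKM in at least 2 libraries were tested, 11069 in all. limma 3.58.1 in R 4.3.3 (limma-trend) was fitted with 1 coefficient for each of the 6 groups, which left 6 residual degrees of freedom and a prior of 4.49. All tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. Knockout was compared with wild type in each population, the populations were compared within each genotype, and the difference between the knockout effects of each pair of populations was tested as an interaction. Folds are ratios on the FPKM + 1 scale, and standard errors (SE) are those of the limma log2 change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

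The tests, the comparisons, the gene lists, the rule for naming genes and the first set of other settings were chosen before the data were examined. There were 30 lists, 24 of cell functions and 6 of other cell types or of the sex of the animal. They held 670 symbols, of which 652 were in the files and 582 were tested. The lists were tested with camera at a preset correlation of 0.01, with adjustment over the 23 function lists that could be tested, and again with an estimated correlation and with fry. A list count is the number of members called over all genes, and the count adjusted over the list alone treats the list as the whole family of tests.

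The rule named Mzb1, Prdm1, Sdc1, Itgb1, Itga4, Itgal, Itgb2, Hsp90b1 and Hspa5 in each comparison. It also named up to 10 genes higher and 10 lower by log2 change in the knockout comparisons and in wild-type plasmablasts against activated B cells, and up to 5 each way elsewhere. These had to be called, to reach a mean of 1 FPKM in the higher group and to have no overlap between the libraries of both groups. From each list the rule took up to 4 called members with the lowest p, or the 2 members with the lowest p where fewer than 2 were called. Interactions gave up to 5 genes each way by p.

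The settings chosen then were no filter, a filter of 5 FPKM, a pseudocount of 0.1, quantile normalization and a fit on the compared groups alone. A replicate block used the replicate number for ko against wt, and the replicate number within each genotype for the other comparisons. Across genes, replicate differences of wt and ko correlated at -0.11, -0.08 and -0.05 in the 3 populations, which gives no sign of pairing across genotypes. Another setting was a correlation within replicate number of the same genotype (duplicateCorrelation, run with limma-trend). The last were a minimum log2 change of 1 and leaving out each library in turn. Where 1 library remained in a group, its spread was assumed to be that of the other groups. Further settings were chosen after the data had been seen. They were a term for the fragment pattern described with the libraries, the libraries of the first pattern alone, leaving out wt replicate 1 in all 3 populations, rescaling to equal totals over genes other than small RNA genes, and leaving out small RNA genes. For a gene called under neither setting, a change of sign was counted as no change. Tools that need counts could not be used.

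The fragment pattern was read from genes below 0.5 FPKM. For each pair of libraries, the share of such genes at the most frequent ratio of values was taken with a log2 tolerance of 0.002, since libraries quantified with the same effective gene lengths give most genes with 1 fragment the same ratio.

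The model was tested on simulated data with 200 changed genes and 2 libraries per group. It called 37.3% of true log2 changes of 0.5 in activated B cells, 47.8% in pre-plasmablasts and 44.8% in plasmablasts. For changes of 1 these shares were 95.5%, 91.0% and 92.5%, and all changes of 2 were called. Unchanged genes were called 8, 11 and 17 times. Over 20 simulations of the plasmablast comparison, unchanged genes made up 4.87% of the calls. Of 200 simulated lists without a shift, 2.5% had a camera p below 0.05. The simulated genes varied independently, so this share does not show how camera performs where members of a list vary together. The simulated libraries also carried no fragment pattern and no difference between animals. The shares of changed and unchanged genes called therefore do not show how many real calls come from either.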

Results

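The 12 libraries held between 418966 and 581262 FPKM in total, and 10180 to 10466 genes reached 1 FPKM in each. Between 10170 and 10936 genes were listed at 0. Small RNA genes, of which 1277 are listed and 37 were tested, took 0.981% to 14.2% of the total, with the highest share in ko pre-plasmablast replicate 2. Across genes, which are not independent replicates, the log2 values of the 2 libraries of a group correlated with r between 0.984 and 0.989.

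The libraries differed in 2 ways that the groups do not name. Low values followed 1 fragment pattern (A) in 8 libraries, which were all wt libraries and replicate 1 of ko activated B cells and of ko pre-plasmablasts. The other 4 libraries, replicate 2 of those ko groups and both ko plasmablast libraries, followed another (B). Pairs of libraries shared a ratio in 8.95% to 20.5% of low genes within A, in 6.86% to 16.4% within B and in 2.02% to 4.52% across A and B. In plasmablasts the pattern therefore separated the genotypes fully. Read from the same ratios against wt plasmablast replicate 1, relative depth differed among the pattern A libraries. It ran from 0.928 in wt plasmablast replicate 2 to 1.83 in ko activated B cell replicate 1. Across the patterns few genes shared a ratio, so depth could not be compared well there. The other difference was the sex-linked transcripts. Xist, transcribed from the inactive X chromosome, was at 81.4, 35.3 and 33.3 FPKM in replicate 1 of wt activated B cells, pre-plasmablasts and plasmablasts, and the Y-linked genes Eif2s3y, Kdm5d and Uty were listed at 0 there. In the other 9 libraries Xist lay between 0.0151 and 0.389 FPKM and Y-linked Ddx3y between 15.7 and 22.0 FPKM.

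The first question was whether the knockout libraries lacked Mzb1, an endoplasmic reticulum (ER) protein of B cells that works with the chaperone Hsp90b1. In wt cells Mzb1 rose from 931 ± 121 FPKM in activated B cells (SD, n = 2) to 9996 ± 99.0 in pre-plasmablasts and 16396 ± 1361 in plasmablasts. The last step (log2 change 0.71) turned to -0.51 with quantile normalization. In ko cells it stood at 281 ± 11.9, 885 ± 19.9 and 967 ± 57.8 FPKM. The limma log2 change of ko against wt was -1.72 (SE 0.13, adjusted p = 0.000325), -3.50 (adjusted p = 4.66e-07) and -4.08 (adjusted p = 9.37e-08). The 2 wt plasmablast libraries had 15434 and 17359 FPKM and the ko libraries 926 and 1008, a 16.9-fold difference. Transcripts assigned to Mzb1 were still present in each ko library.

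**Figure D1:**
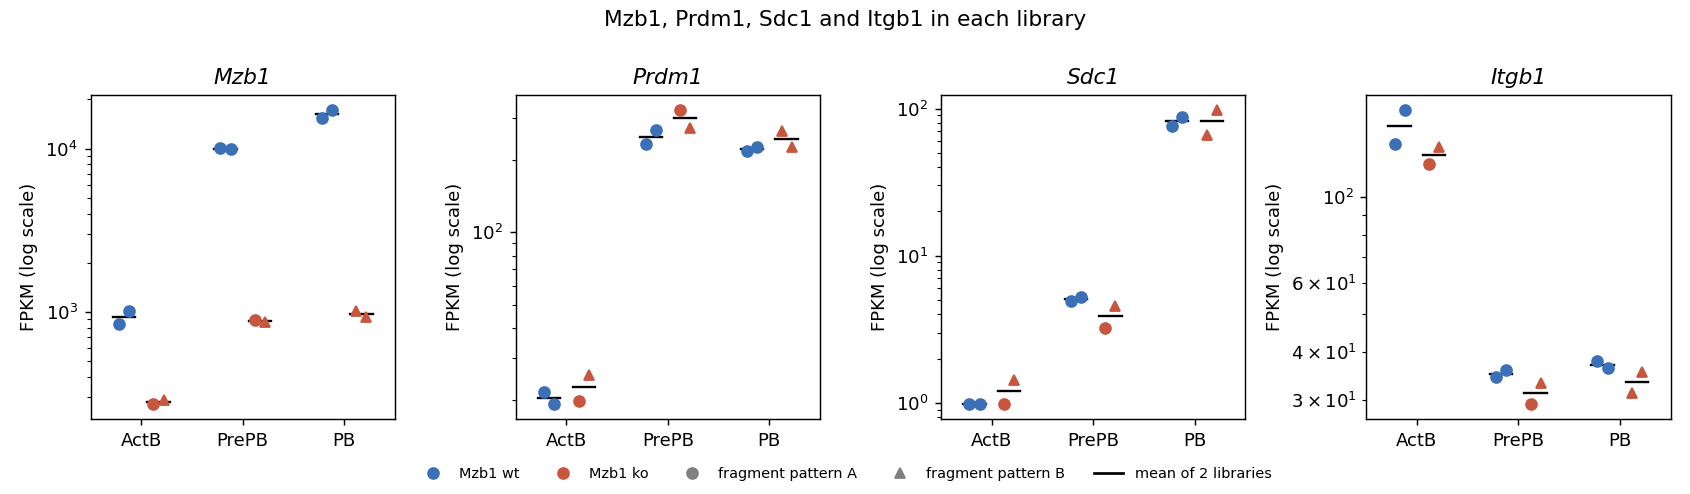
FPKM on a log axis of Mzb1, Prdm1, Sdc1 and Itgb1 in the 12 libraries, by population and genotype (wt blue, ko red); circles are libraries of fragment pattern A, triangles those of pattern B, and black lines are means of 2 libraries. Mzb1 was lower in ko in each population, while the other genes moved between populations and their ko and wt means were close.

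The comparison of wt plasmablasts with wt activated B cells shows what differentiation toward antibody secretion changed in this culture. Plasmablasts had far more RNA for protein secretion and for plasma cell regulators, and far less for B cell identity and the actin cytoskeleton. Jchain, which joins immunoglobulin M and A polymers, rose from 86.2 ± 23.8 to 20835 ± 2520 FPKM (SD, n = 2), 243-fold. Sdc1, which encodes the sorting marker CD138, rose 41.9-fold from 0.983 to 82.3 FPKM, and Prdm1 rose 10.4-fold from 20.4 to 222 FPKM. Differences in Sdc1 and Prdm1 between the populations are partly set by the sort, which used CD138 and the Prdm1 reporter. Xbp1, the transcription factor of the secretory programme, rose 23.6-fold from 102 to 2441 FPKM. limma called 6864 genes, 3432 higher and 3432 lower, of which 2456 changed by at least 1 on the log2 scale. Rescaled to equal totals, which moved the median of all genes to -0.38 from -0.014, the split was 2149 higher and 5773 lower.

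The largest rises also included the secreted protease inhibitor Slpi (8.18), the inhibitory receptors Tigit (6.47) and Lag3 (5.48), the ER prolyl isomerase Fkbp11 (6.29), the kinase subunit Pik3cg (5.97), the vesicle protein Hid1 (5.46), the protease inhibitor Spint2 (5.26) and the disulfide isomerase Txndc5 (5.23), all as log2 changes. Slpi differed widely between the replicates, at 3171 ± 2829 FPKM in plasmablasts (SD, n = 2). Among the largest falls were those of the small nucleolar RNA Snord16a, with a log2 change of -10.08, the inhibitory receptor Cd22 (-7.19), the B cell transcription factor Spib (-6.41), Wfdc17 (-6.29), the integrin chain Itgam (-6.07), the transcription factor Klf2 (-5.91), Mpeg1 (-5.86) and the small nucleolar RNA Snora28 (-5.69). Snord16a and Snora28 were listed at 0 in plasmablasts, so their sizes depend on the pseudocount, and the call of Snord16a was lost without wt activated B cell replicate 2. Libraries of the groups did not overlap for any of these genes.

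The secretory lists moved together. All 33 members of the ER folding list rose, among them Xbp1, Derl3 (4.58), which takes part in ER-associated degradation, and Fkbp11 (camera adjusted p = 3.04e-20; adjusted p = 0.122 with an estimated correlation). Of 45 translocon, signal peptidase and vesicle coat genes 44 rose and 1 fell, with Ssr4 at 3.53 and Spcs1 at 3.02 (adjusted p = 2.73e-19; adjusted p = 0.122 with an estimated correlation). N-glycosylation had 32 of 36 members higher and 0 lower, with Ddost at 3.32 and Stt3a at 2.46 (adjusted p = 4.4e-12; adjusted p = 0.144 with an estimated correlation). Adjusted over the list alone the N-glycosylation count was 33. Plasma cell identity had 22 of 23 members higher, with the elongation factors Eaf2 at 4.23 and Ell2 at 3.30 (adjusted p = 2.78e-12; adjusted p = 0.122 with an estimated correlation). Of the ATF4 and CHOP stress response, 15 of 21 members rose and 4 fell, with Chac1 at 2.67 and Slc3a2 at 2.64 (adjusted p = 0.0162; adjusted p = 0.122 with an estimated correlation). Rescaled to equal totals that list had 10 higher and 6 lower, and its call was lost with quantile normalization.

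B cell lists fell. Of 34 B cell identity genes 26 fell and 5 rose, with Pax5, the factor that keeps B cell commitment, at -5.48 and Cd72 at -4.16 (adjusted p = 2.62e-07; adjusted p = 0.122 with an estimated correlation). Of 7 genes known to be repressed by Blimp1, 5 fell and 1 rose, with Ciita, the regulator of MHC class II, at -4.77 (adjusted p = 0.0031; adjusted p = 0.257 with an estimated correlation). MHC class II presentation had 9 of 11 members lower and 2 higher, with H2-Oa at -4.84 (adjusted p = 0.00131; adjusted p = 0.391 with an estimated correlation). Toll-like receptors and LPS recognition had 9 of 16 lower and 4 higher, with Tlr9 at -5.25 (adjusted p = 0.0399; adjusted p = 0.424 with an estimated correlation). The call of that list was lost with the replicate block. NF-kappaB targets had 14 of 24 lower and 5 higher, with Il6 at -3.65 (adjusted p = 0.0205; adjusted p = 0.257 with an estimated correlation). Actin cytoskeleton and migration had 29 of 38 lower and 2 higher, with Tmsb4x, which binds actin monomers, at -2.75 (adjusted p = 1.64e-07; adjusted p = 0.257 with an estimated correlation). Immediate early and heat shock genes went the other way, 12 of 18 higher and 3 lower, with the phosphatase Dusp1 at 3.21 (adjusted p = 0.0031; adjusted p = 0.158 with an estimated correlation). With an estimated correlation 0 of the 23 lists passed in this comparison, against 12 with the preset one and 15 with fry.

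**Figure D2:**
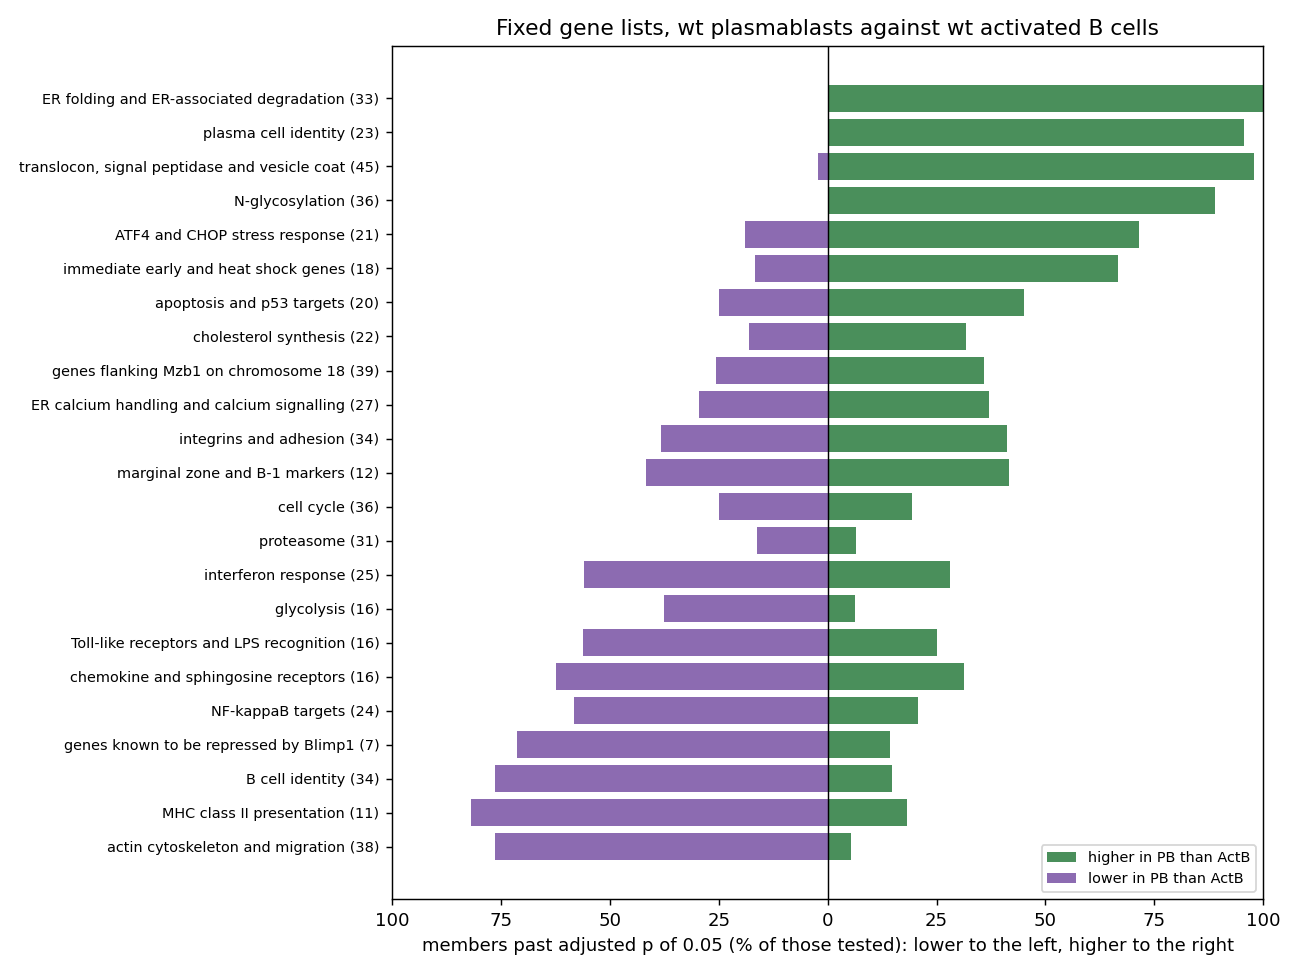
Share of the tested members of each function list called higher (to the right) or lower (to the left) in wt plasmablasts than in wt activated B cells, in percent. The secretory lists lie almost wholly to the right and the B cell and actin lists mainly to the left.

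The title of the series names β1 integrin, and its gene went down with differentiation. Itgb1 stood at 153 ± 22.0 FPKM in wt activated B cells (SD, n = 2), 35.1 ± 1.04 in pre-plasmablasts and 37.0 ± 0.984 in plasmablasts, a 4.03-fold fall to plasmablasts (log2 change -2.01, SE 0.11, adjusted p = 7.63e-08). Itga4, the α4 chain that pairs with β1 or β7, went the other way, from 17.0 to 69.8 FPKM (1.98, adjusted p = 2.19e-06). Itgb2, the β2 chain, rose from 70.6 to 155 FPKM (1.13, adjusted p = 3.03e-05), and Itgal, its partner in LFA-1, had 107 and 128 FPKM (0.26, adjusted p = 0.0622). Itgal was called with the replicate block, with duplicateCorrelation and with a term for the fragment pattern. Itgb5 rose by 3.18, the selectin ligand gene Selplg rose by 2.18, and the β7 chain Itgb7 had a log2 change of -2.93. As a list, 14 of 34 integrin and adhesion genes rose and 13 fell, and camera found no common direction (adjusted p = 0.998).

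The other function lists did not pass in this comparison. Chemokine and sphingosine receptors had 5 of 16 higher and 10 lower (adjusted p = 0.156), with Ccr7 at -5.04. Calcium handling had 10 of 27 higher and 8 lower (0.921), cell cycle 7 of 36 higher and 9 lower (0.364), apoptosis and p53 targets 9 of 20 higher and 5 lower (0.333), and the interferon response 7 of 25 higher and 14 lower (0.325). Cholesterol synthesis had 7 of 22 higher and 4 lower (0.406), glycolysis 1 of 16 higher and 6 lower (0.212), and the proteasome 2 of 31 higher and 5 lower (0.565). Marginal zone and B-1 markers had 5 of 12 each way (0.93), and the genes flanking Mzb1 had 14 of 39 higher and 10 lower (0.565). Rescaling to equal totals gave 0 higher and 24 lower for the cell cycle and 0 higher and 25 lower for the proteasome, and turned the mean of the calcium, cholesterol, marginal zone and flanking lists. Markers of other cell types moved both ways. T cell markers had 2 of 6 higher and 2 lower, macrophage and granulocyte markers 1 of 5 higher and 3 lower, dendritic cell markers 1 of 3 higher and 2 lower, and 1 of 3 natural killer markers was higher (Eomes, 2.70).

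The comparison of pre-plasmablasts with activated B cells asks what differs in cells that have turned on Blimp1 but not CD138. Against wt activated B cells, limma called 5910 genes in wt pre-plasmablasts, 2999 higher and 2911 lower. Prdm1 was 11.7-fold higher, at 250 ± 24.5 FPKM (SD, n = 2), Jchain 107-fold higher and Xbp1 15.2-fold higher, while Sdc1 reached 5.07 FPKM. The largest log2 rises were Slpi (6.90), Jchain (6.74), Lag3 (5.53), the eosinophil granule protein gene Prg2 (5.43) and Fkbp11 (5.11), and the largest falls included Snora28 (-5.69), Snora15 (-5.67), Spib (-4.88) and S100a4 (-4.86). The call of Snora15 was lost without any single library of these groups. All 33 ER folding genes rose (adjusted p = 1.01e-23; adjusted p = 0.131 with an estimated correlation), and 25 of 34 B cell identity genes fell while 6 rose (adjusted p = 5.53e-06; adjusted p = 0.131 with an estimated correlation), with Pax5 at -3.35. Itgb1 was 4.24-fold lower. Rescaling to equal totals gave 2108 genes higher and 4679 lower.

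Between wt pre-plasmablasts and wt plasmablasts the step was smaller. Sdc1 rose 13.7-fold, from 5.07 ± 0.233 to 82.3 ± 8.38 FPKM (SD, n = 2), and Prdm1 was level, at 250 and 222 FPKM (log2 change -0.17, adjusted p = 0.49). Tnfrsf17, the receptor BCMA that supports plasma cell survival, rose by 2.76 on the log2 scale, Nrg2 by 1.82, Gm21975 by 1.63 and the actin bundling gene Pls1 by 1.58. The lipid carrier gene Apoe (-3.74), the lymphotoxin chain Ltb (-3.61), the phosphodiesterase Pde2a (-3.42) and Cd22 (-2.70) were among the largest falls. Plasma cell identity had 10 of 23 members higher and 0 lower (camera adjusted p = 5.07e-09; adjusted p = 0.161 with an estimated correlation), B cell identity 12 of 34 lower and 0 higher (3.02e-09; adjusted p = 0.161 with an estimated correlation), and MHC class II 9 of 11 lower (5.07e-09; adjusted p = 0.185 with an estimated correlation). ER folding had 11 of 33 higher (3.64e-08; adjusted p = 0.282 with an estimated correlation), with Fkbp11 at 1.18 and Txndc5 at 1.12. limma called 966 genes, 556 higher and 410 lower. With a block for the replicate, which pairs libraries of the same replicate number, it called 1558. Leaving out a single library gave 382 without wt pre-plasmablast replicate 1, 364 without its replicate 2, 418 without wt plasmablast replicate 1 and 248 without its replicate 2, and rescaling to equal totals gave 315 genes higher and 1142 lower.

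Knockout cells were then compared across the same steps. limma called 5996 genes between ko pre-plasmablasts and ko activated B cells (3003 higher, 2993 lower), 1196 between ko plasmablasts and ko pre-plasmablasts (727 and 469), and 6880 between ko plasmablasts and ko activated B cells (3458 and 3422). In ko plasmablasts Jchain rose by 9.49 against activated B cells, Slpi by 8.70, Fkbp11 by 7.13, Hid1 by 6.12 and Tigit by 5.90. The largest falls included Mir142b (-6.16), Cd22 (-5.96) and Itgam (-5.56). The call of Mir142b was lost with no filter and without ko activated B cell replicate 2 or either ko plasmablast library. From pre-plasmablasts to plasmablasts, Sdc1 rose by 4.08 and Tnfrsf17 by 2.95, and Ltb (-3.37) and Pde2a (-3.22) fell. From activated B cells to pre-plasmablasts, Jchain rose by 8.08 and Prg2 by 5.64, and Spib (-4.93) and Mpeg1 (-4.43) fell. Of the genes called in both genotypes, 5146 of 5147 changed with the same sign from activated B cells to pre-plasmablasts, 694 of 694 from there to plasmablasts, and 6112 of 6114 from activated B cells to plasmablasts. If the calls in wt and ko were independent, 1072 shared higher and 1061 shared lower genes would come of the last of these, where 3101 and 3011 were found. Across genes the log2 changes of wt and ko correlated with r of 0.94, 0.67 and 0.96 over these 3 steps. Rescaled to equal totals the 3 ko comparisons had 2391 higher and 3976 lower, 389 higher and 1025 lower, and 2445 higher and 5099 lower genes. The count of 1196 fell to 383 without ko pre-plasmablast replicate 1, 632 without its replicate 2 and 377 without ko plasmablast replicate 2.

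The knockout comparisons ask what loss of Mzb1 changed within each sorted population. Across all 3 populations, Coro2a, a coronin that binds actin, was almost absent from ko cells and Tusc1, a gene named as a tumour suppressor candidate, was higher. Coro2a stood at 24.7 ± 10.8 FPKM in wt activated B cells (SD, n = 2) against 0.556 ± 0.212 in ko, at 60.8 ± 23.6 against 0.917 ± 0.278 in pre-plasmablasts and at 54.0 ± 22.9 against 0.973 ± 0.265 in plasmablasts. These were log2 changes of -3.98, -4.96 and -4.74 (adjusted p = 0.00119, 0.000203 and 0.000214). The 2 wt replicates differed too, with 0.527, 0.569 and 0.539 times as much Coro2a in replicate 1 as in replicate 2. Tusc1 had 3.63 ± 0.259, 2.31 ± 0.308 and 2.54 ± 0.134 FPKM in wt against 10.7 ± 1.2, 8.78 ± 1.52 and 7.66 ± 1.57 in ko, which were log2 changes of 1.33, 1.56 and 1.28 (adjusted p = 0.0134, 0.00275 and 0.00752). Of 52 genes called in any population, 3 were called in all, and these were Mzb1, Coro2a and Tusc1. The call of Tusc1 was lost in activated B cells without any single library of those 2 groups, and in plasmablasts without wt replicate 1, wt replicate 2 or ko replicate 1.

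**Figure D3:**
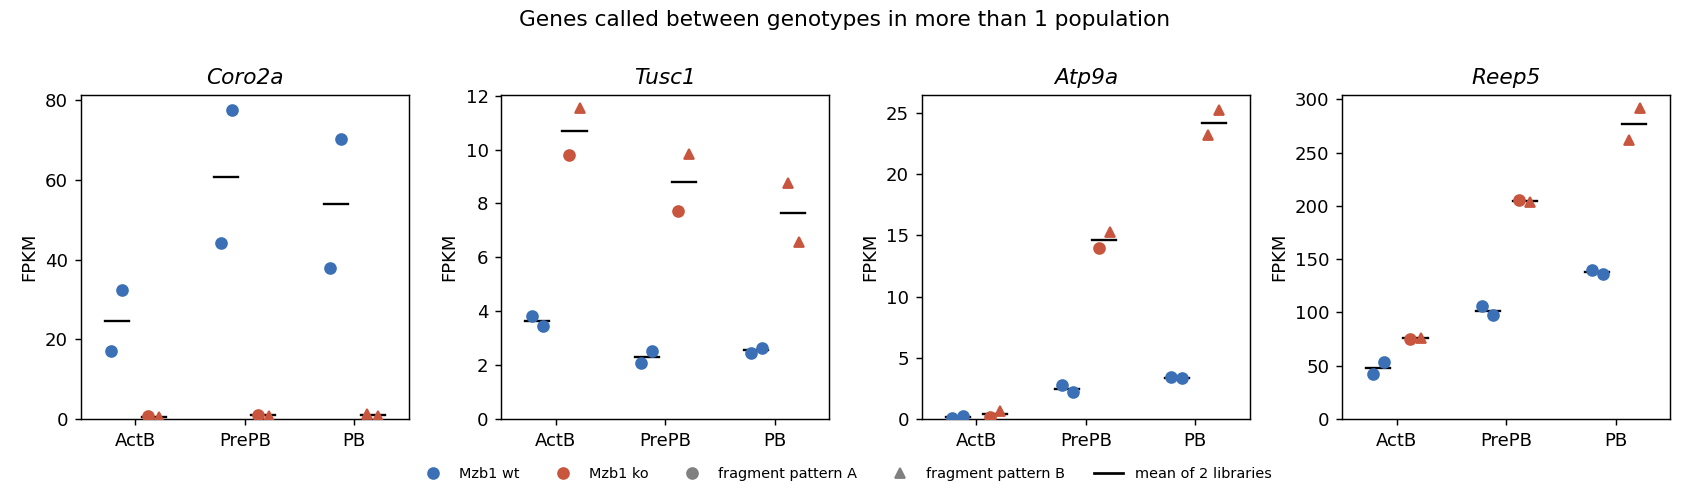
FPKM on linear axes of Coro2a, Tusc1, Atp9a and Reep5 in the 12 libraries, by population and genotype (wt blue, ko red); circles are libraries of fragment pattern A, triangles those of pattern B, and black lines are means of 2 libraries. Coro2a was near 0 in each ko library, and Atp9a was higher in ko pre-plasmablasts and plasmablasts.

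In activated B cells limma called 6 genes, 2 higher and 4 lower in ko. Besides Mzb1, Coro2a and Tusc1, they were Pira4 (log2 change 1.47) and Pira7 (-1.56), which belong to a family of near-identical paired receptors, and the small nucleolar RNA Snora28 (-5.69), which was at 54.8 ± 30.2 FPKM in wt (SD, n = 2) and listed at 0 in ko. The ER folding list lay lower, with 0 of 33 members called, 4 lower when adjusted over the list alone, and a positive change in 3 (mean -0.18; adjusted p = 1.86e-09; adjusted p = 0.35 with an estimated correlation). Its chaperone Hsp90b1 had 598 ± 11.7 FPKM in wt and 438 ± 26.0 in ko (-0.45, adjusted p = 0.433) and Hspa5 had 477 ± 20.7 and 378 ± 25.9 (-0.34, adjusted p = 0.499). Without a called member other than Mzb1, 6 further lists passed downward, which were the proteasome (1.86e-09; adjusted p = 0.35 with an estimated correlation), translocon (2.53e-06; 0.398), plasma cell identity (0.00135; 0.35), glycolysis (0.00435; 0.398), cell cycle (0.0121; 0.633) and ATF4 and CHOP (0.0254; 0.35). Plasma cell identity includes Mzb1, whose fall follows from the knockout, and was not tested without it. Upward passed B cell identity (0.00132; 0.35), NF-kappaB targets (0.00455; 0.35) and apoptosis (0.0178; 0.35), with the second value in each case again the adjusted p with an estimated correlation. Among these lists, ATF4 and CHOP lost its call without wt replicate 1, wt replicate 2 or ko replicate 2, glycolysis without wt replicate 1, apoptosis without wt replicate 1 or ko replicate 1, and B cell identity without ko replicate 2. Cell cycle lost its call without wt replicate 1 and turned without ko replicate 2. The call of Pira4 was lost without wt replicate 1, ko replicate 1 or ko replicate 2, and that of Pira7 without wt replicate 2, ko replicate 1 or ko replicate 2. The count of 6 became 3 without ko activated B cell replicate 1, and the libraries of pattern A alone gave 7, of which 2 were shared.

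In pre-plasmablasts limma called 13 genes, 11 higher and 2 lower in ko. Atp9a, a flippase-related membrane ATPase, stood at 2.48 ± 0.362 FPKM in wt and 14.6 ± 0.948 in ko (SD, n = 2), 4.50-fold higher (SE 0.17 on the log2 scale, adjusted p = 0.000472). Itgam, the CD11b integrin chain of myeloid cells and some B cells, stood at 2.95 ± 0.696 and 13.2 ± 1.60 FPKM (1.85, adjusted p = 0.000994). Reep5, which shapes ER tubules, was 2.01-fold higher, at 205 against 102 FPKM. The others by the rule were the transcription factor Sox4 (1.44), A630023P12Rik (1.67), the growth hormone gene Gh (2.37-fold), the sphingolipid transporter relative Spns3 (1.13), the complement regulator properdin Cfp (1.02) and the phospholipase Plcb2 (0.99). Macrophage and granulocyte markers were higher in ko, with a mean of 0.87 over 5 tested and 1 called, Itgam itself (camera adjusted p = 0.00028; adjusted p = 0.0314 with an estimated correlation). B cell identity lay higher with 0 of 34 called and 2 when adjusted over the list alone (adjusted p = 0.00103; adjusted p = 0.609 with an estimated correlation). The proteasome lay lower with 0 of 31 called and 0 positive (3.37e-09; adjusted p = 0.609 with an estimated correlation), as did plasma cell identity, in which Mzb1 itself was the 1 called (0.0177; adjusted p = 0.616 with an estimated correlation), and the translocon list (0.0388; adjusted p = 0.812 with an estimated correlation), whose mean of -0.07 turned under equal totals. The fall of Mzb1 follows from the knockout, and plasma cell identity was not tested without it. The translocon call was lost without wt replicate 2 or either ko replicate, and that of plasma cell identity without wt replicate 2 or with quantile normalization. Cfp, Gh, Plcb2 and Spns3 lost their call without any single library of these groups, Sox4 without wt replicate 1, wt replicate 2 or ko replicate 1, A630023P12Rik without wt replicate 1 or either ko replicate, and Reep5 without wt replicate 2. The count of 13 fell to 7 without wt replicate 1, 7 without wt replicate 2, 7 without ko replicate 1 and 8 without ko replicate 2, and pattern A alone gave 11 genes, 5 of them shared.

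In plasmablasts, 5 genes of the B cell programme were higher in ko than in wt, at levels below those of activated B cells. Pax5 stood at 2.39 ± 0.521 FPKM in wt and 6.58 ± 0.933 in ko (SD, n = 2), 2.24-fold higher (log2 change 1.17, SE 0.12, adjusted p = 0.0031), against 149 in wt activated B cells. Spib had 4.14 ± 0.323 and 13.6 ± 5.15 FPKM (1.46, adjusted p = 0.0148), the follicle homing receptor Cxcr5 7.76 ± 0.502 and 16.1 ± 2.68 (0.95, adjusted p = 0.00539), the inhibitory receptor Cd72 7.39 ± 0.715 and 14.8 ± 0.782 (0.91, adjusted p = 0.0148) and the kinase Blk 77.8 ± 5.96 and 115 ± 6.39 (0.56, adjusted p = 0.0419). These were the 5 of 34 B cell identity genes called, all higher, and 27 had a positive change (8 higher when adjusted over the list alone; camera adjusted p = 3.21e-06; adjusted p = 0.251 with an estimated correlation). Blk lay outside the rule for naming genes and was chosen after its values were seen. With a term for the fragment pattern none of these 5 was called, at adjusted p from 0.113 to 0.302. The calls of Spib and Cd72 were lost without wt replicate 1, wt replicate 2 or ko replicate 1, and that of Cxcr5 without wt replicate 2.

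**Figure D4:**
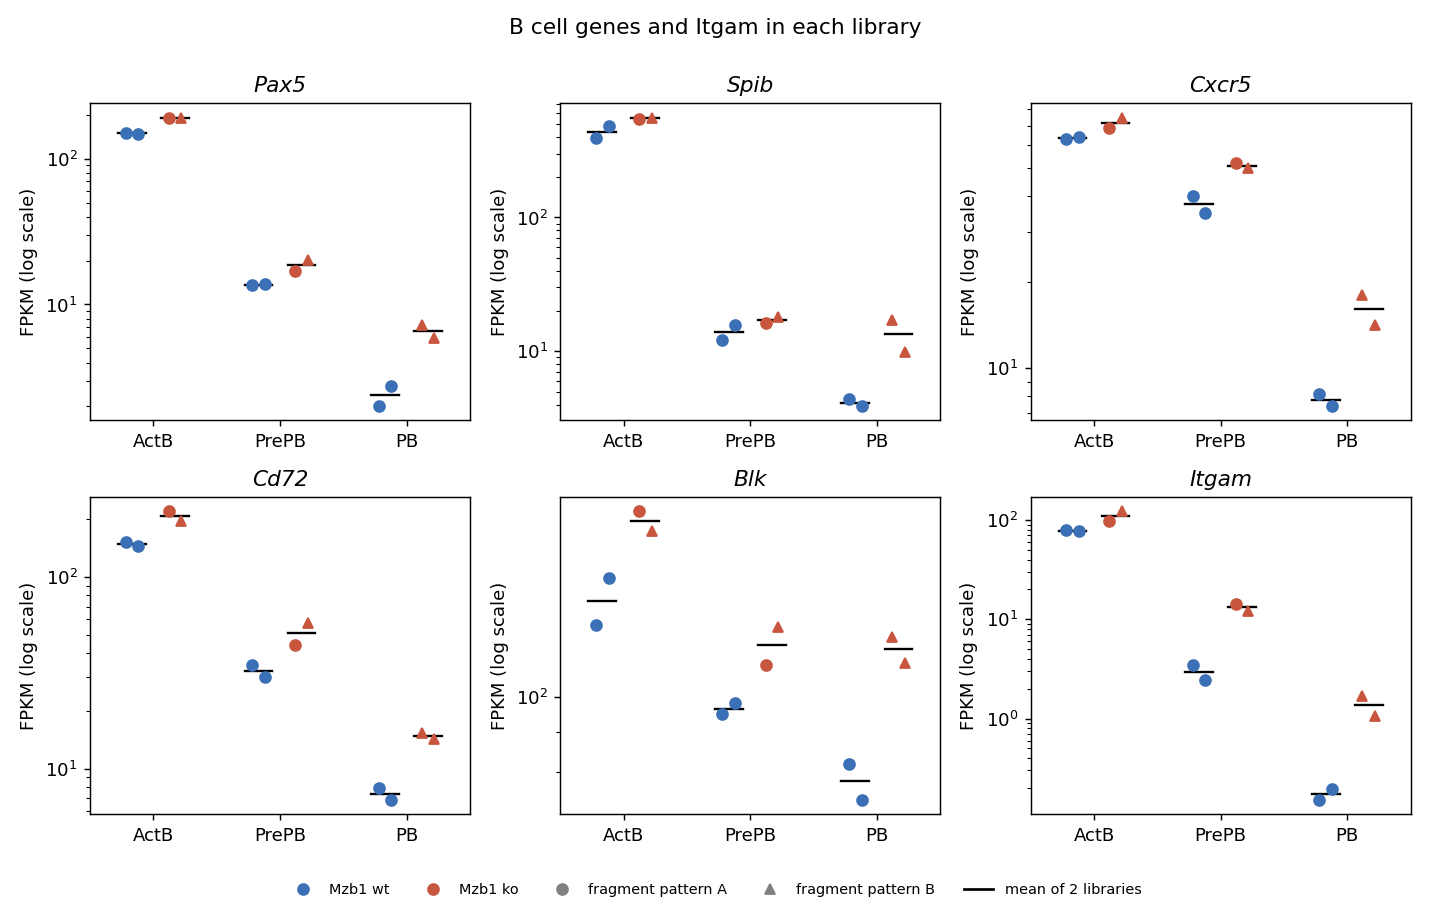
FPKM on log axes of Pax5, Spib, Cxcr5, Cd72, Blk and Itgam in the 12 libraries, by population and genotype (wt blue, ko red); circles are libraries of fragment pattern A, triangles those of pattern B, and black lines are means of 2 libraries. In plasmablasts both ko libraries lay above both wt libraries for each gene, and all 4 plasmablast libraries lay below the activated B cells of the same genotype.

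Other lists passed in ko plasmablasts with few called members. Genes known to be repressed by Blimp1 had 2 of 7 higher, Pax5 and Spib (adjusted p = 0.00983; adjusted p = 0.406 with an estimated correlation). MHC class II had 1 of 11, H2-Oa (1.07), and 7 when adjusted over the list alone (0.000769; adjusted p = 0.406 with an estimated correlation). Chemokine receptors had 1 of 16, Cxcr5, and 6 adjusted over the list alone (0.000649; adjusted p = 0.251 with an estimated correlation), and Toll-like receptors 1 of 16, the DNA sensor Tlr9 (0.74; list 0.00983; adjusted p = 0.406 with an estimated correlation). Immediate early genes passed upward with 0 of 18 called (0.0132; adjusted p = 0.406 with an estimated correlation). Downward passed the proteasome with 0 of 31 called and 2 positive (4.2e-08; adjusted p = 0.406 with an estimated correlation), glycolysis (0.0416; adjusted p = 0.656 with an estimated correlation) and cholesterol synthesis (0.0218; adjusted p = 0.656 with an estimated correlation), in which the sterol carrier Stard4 was called higher. Glycolysis lost its call without wt replicate 1, ko replicate 1 or ko replicate 2, and with quantile normalization. Cholesterol synthesis lost its call without wt replicate 1 or ko replicate 1, and immediate early genes without wt replicate 2 or ko replicate 1. The Blimp1-repressed list lost its call without ko replicate 1, Toll-like receptors without ko replicate 2 or with the pattern term, and MHC class II with the pattern term. ER folding had 0 of 33 called (0.668). Macrophage markers had a mean of 0.85 (adjusted p = 0.00167; adjusted p = 0.0529 with an estimated correlation), and of the T cell, natural killer, dendritic and erythroid markers 0 were called in any knockout comparison.

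Of the 45 genes that limma called in plasmablasts, 29 were higher and 16 lower in ko, and 20 changed by at least 1. The largest rises by the rule were Atp9a, from 3.38 ± 0.0678 to 24.2 ± 1.45 FPKM (SD, n = 2; 2.52), Spib, Cxx1c (1.37), Tusc1, Pde2a (1.18), Pax5, 2300009A05Rik (from 8.31 to 19.1 FPKM), the proton channel Hvcn1 (1.11) and H2-Oa, and 1700041A01Rik, which was listed at 0 in wt. The largest falls, after Mzb1 and Coro2a, were the splicing factor gene Snrpg (-1.22), the nucleolar methyltransferase gene Fbl (-1.22), Hist1h2bb (-1.15), the RNA binding protein gene Hnrnpa1 (-1.11), the cell cycle inhibitor locus Cdkn2a (-1.06), Tpt1 (-1.05), the ribosomal protein gene Rpl6 (from 55.0 to 27.0 FPKM) and Bcl2l15 (-0.98). The interferon-induced Isg15 was lower (-0.81, adjusted p = 0.0063) in a list that did not pass (0.257). Leaving out 1 library gave 11 genes without wt replicate 1, 11 without wt replicate 2 and 10 without ko replicate 1. The calls of Mzb1, Coro2a, Atp9a, Pax5, Rpl6 and Bcl2l15 remained without each of the 4 plasmablast libraries in turn.

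The fragment pattern bears on this count most. No value within a pattern can be had for plasmablasts, since both ko libraries are of pattern B and both wt libraries of pattern A. With a term for the pattern, which the other populations estimate, limma called 4 genes (Atp9a, Coro2a, Mzb1 and Snord16a), of which 3 were among the 45. All 45 kept their sign, with the median absolute log2 change going from 0.98 to 0.89 and the median SE from 0.13 to 0.18.

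The regulators and surface markers that define the populations did not differ detectably between genotypes. Cells were sorted on the Prdm1 reporter and CD138, so likeness of Prdm1 and Sdc1 within a gate is partly set by the sort. This likeness does not show whether ko cells turned on either gene as often as wt cells. Prdm1 had 250 ± 24.5 FPKM in wt and 298 ± 37.0 in ko pre-plasmablasts (SD, n = 2; log2 change 0.25, SE 0.13, adjusted p = 0.418) and 222 ± 5.51 and 245 ± 26.0 in plasmablasts (0.14, adjusted p = 0.66). Sdc1 had 82.3 ± 8.38 and 82.4 ± 22.6 FPKM in plasmablasts (-0.02, SE 0.19, adjusted p = 0.972). Xbp1 had 2441 and 2022 FPKM there (-0.27, SE 0.09, adjusted p = 0.208), and Jchain 20835 ± 2520 and 17914 ± 2285 (-0.22, SE 0.35, adjusted p = 0.8). For Hsp90b1 the plasmablast means were 5326 ± 231 and 5087 ± 542 FPKM (-0.07, adjusted p = 0.828) and for Hspa5 2420 ± 140 and 2679 ± 104 (0.15, adjusted p = 0.57). Itgb1 had 37.0 ± 0.984 FPKM in wt and 33.4 ± 2.88 in ko plasmablasts (-0.15, SE 0.11, adjusted p = 0.552), with changes of -0.24 in activated B cells (adjusted p = 0.622) and -0.17 in pre-plasmablasts (adjusted p = 0.505). Itga4 (-0.03, adjusted p = 0.948), Itgal (0.07, adjusted p = 0.79) and Itgb2 (0.20, adjusted p = 0.501) were not called in plasmablasts either. Of 34 integrin and adhesion genes, Itgam was the 1 called in ko pre-plasmablasts and in ko plasmablasts (list adjusted p in plasmablasts 0.257). Its plasmablast call was lost without wt replicate 1, wt replicate 2 or ko replicate 1, with quantile normalization and with the pattern term.

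Whether the knockout effect differed between populations was tested directly. Between pre-plasmablasts and activated B cells limma called 4 genes, Mzb1, Atp9a, Cdkn2a and Snora28, and between plasmablasts and activated B cells 5, the same 4 and Tpt1. Cdkn2a had 24.5 ± 1.12 FPKM in wt and 48.4 ± 1.26 in ko activated B cells (SD, n = 2), but 191 ± 20.7 and 91.9 ± 16.0 in plasmablasts, an interaction of -2.01 (SE 0.23, adjusted p = 0.0128). That call was lost with no filter and without either wt library of these 2 populations or replicate 1 of either ko group, each left out alone. Between plasmablasts and pre-plasmablasts limma called 0 genes, with 272 at an unadjusted p below 0.05, so a B cell gene called in plasmablasts and not in pre-plasmablasts is not shown to differ between them. The count of 4 fell to 2 without wt activated B cell replicate 1 and to 1 without ko activated B cell replicate 1, wt pre-plasmablast replicate 1 or wt pre-plasmablast replicate 2. The count of 5 became 10 without ko activated B cell replicate 2, 2 without wt activated B cell replicate 1 or wt plasmablast replicate 2, and 3 without ko activated B cell replicate 1, ko plasmablast replicate 1 or ko plasmablast replicate 2. The 0 became 1 without ko pre-plasmablast replicate 2.

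The knockout changes of the populations resembled each other. Of the 45 genes called in plasmablasts, 44 had the same sign in pre-plasmablasts and 41 in activated B cells, and 9 were also called in pre-plasmablasts (7 higher and 2 lower). Across the 11069 genes the log2 changes correlated with r = 0.40 between pre-plasmablasts and activated B cells (Spearman 0.45), 0.47 between plasmablasts and pre-plasmablasts (0.61) and 0.45 between plasmablasts and activated B cells (0.43). The covariances were 0.0295, 0.0403 and 0.0341, where deviations shared by libraries of the same replicate number alone would give 0.00893, 0.0109 and 0.00925. Genes are not independent replicates. The labels give replicate numbers and no animals, but the sex-linked transcripts of the wt libraries followed the replicate number, so the populations seem to share animals and this likeness is not independent evidence.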

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

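The tests of explanations in this part were chosen after the results were seen, and the tests of a difference between populations were planned. The thresholds that pick the reference genes for carried-over cells were set after several settings had been looked at, and the B cell genes were divided by the share that each needed. Those reference genes were also chosen for low values in wt plasmablasts, which raises their shares by chance, so a share above their range counts against carried-over cells and a share within it decides nothing. A second reference set, tried as well and scarce by the mean of wt and ko plasmablasts, had 90th percentiles of 2.45% for activated B cells (37 genes) and 15.3% for pre-plasmablasts (5 genes). By it Cd72 (3.71%) would lie above the first, and Pax5 (25.8%), Cxcr5 (19.2%) and Cd72 (17.0%) above the second. Since its rule limits the share that a gene can show, it was not used to exclude, and the verdict on these genes depends on the set. Most reference genes had a positive share, 44 of 46 for activated B cells and 14 of 14 for pre-plasmablasts in the first set. In the second these were 35 of 37 and 5 of 5. Reference genes were thus generally higher in ko than in wt plasmablasts, and Pax5 (2.23%) and Spib (1.73%) lay within their activated B cell range. The activated B cell median of the second set was 2.09% in ko replicate 1 and 0.594% in replicate 2.

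limma called an interaction of the change with loss of Mzb1 and the population for 5 genes. Between pre-plasmablasts and activated B cells the differences in log2 change were -1.78 for Mzb1 (adjusted p = 0.00697), 1.89 for Atp9a (0.0465), -1.75 for Cdkn2a (0.0466) and 5.69 for Snora28 (0.000417). Between plasmablasts and activated B cells they were -2.36 for Mzb1 (0.000434), 2.25 for Atp9a (0.00953), -2.01 for Cdkn2a (0.0128), 5.69 for Snora28 (0.000417) and -1.30 for Tpt1 (0.0194). Snora28 was listed at 0 outside wt activated B cells, so its value depends on the pseudocount. Most of these calls were lost when 1 of the 8 libraries was left out. Between pre-plasmablasts and activated B cells this held for Atp9a and for Cdkn2a with 7 of the libraries and for Mzb1 with 3. Between plasmablasts and activated B cells it held for Cdkn2a with 6, Tpt1 with 6 and Atp9a with 5, and the calls of Mzb1 and Snora28 remained.

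The change also differed for several lists when tested with the preset correlation, though with 0 members called in each. Between pre-plasmablasts and activated B cells the mean difference was 0.20 for ER folding (adjusted p = 5.16e-08), -0.14 for apoptosis and p53 targets (0.00694) and 0.51 for macrophage and granulocyte markers (0.00576). Between plasmablasts and pre-plasmablasts it was 0.16 for B cell identity (0.0254), 0.37 for genes known to be repressed by Blimp1 (0.0150), 0.21 for MHC class II (0.0150), 0.17 for chemokine receptors (0.0492) and 0.12 for Toll-like receptors (0.0254). Between plasmablasts and activated B cells it was 0.22 for ER folding (6.54e-08), 0.23 for B cell identity (0.00356), 0.33 for MHC class II (0.000457), 0.34 for chemokine receptors (0.000228) and -0.15 for apoptosis (0.00218). With an estimated correlation 0 of the function lists passed in these 3 tests, with a lowest adjusted p of 0.654, 0.848 and 0.334, and the macrophage list had an adjusted p of 0.0804.

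For the first pattern, the higher level of Pax5, Spib, Cxcr5, Cd72 and Blk in ko plasmablasts, the fragment pattern of the libraries cannot be decided, since it separates the genotypes fully there. Its term rests on replicate 2 against replicate 1 of ko activated B cells and ko pre-plasmablasts. It therefore cannot be told apart from a difference between those replicates, and its size in plasmablasts is assumed to be the same. The term had a median of 0.085 on the log2 scale and an upper 95% limit of at most 0.553, below the change of each of the 5 genes. With the pattern term their median change went from 0.95 to 0.92 while the median SE rose from 0.12 to 0.17; with the first SE all 5 stayed called at the second changes, and with the second SE 0 were called at the first. Activated B cells carried into the ko plasmablast gate are argued against for Cxcr5 and Blk, which needed a share of at least 12.95% where 46 other genes abundant in activated B cells had a 90th percentile of 3.89%, and they cannot be decided for Pax5, Spib and Cd72, which needed a median of 2.23%. Carried-over pre-plasmablasts are argued against for Spib and Blk, which needed at least 72.8% against a 90th percentile of 36.7% over 14 reference genes, and cannot be decided for Pax5, Cxcr5 and Cd72, which needed a median of 19.2%. The fragment pattern, a mixture of both cell types, which was not tested, an effect of Mzb1 itself and differences between the mice stay open.

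The second pattern is the set of genes called between the genotypes in any population, which may hold passengers of the Mzb1 allele or of other variants between the animals. Of the 100 tested genes nearest to Mzb1, 2 were called (Stard4 and Reep5; Fisher's exact p = 0.0708), while the fixed list of flanking genes had 0 of 39 called by limma in any of the populations; the wider window was chosen once Stard4 and Reep5 had been noticed. Of the 46 called genes with a known position, 10 had another within 20 tested genes, against a mean of 7.14 for random genes (permutation p = 0.25, 10000 permutations). They were Stard4, Reep5, Cd72, Pax5, Cdkn2a, Tusc1, Rpl6, Hvcn1, Spib and Il4i1. The B cell genes Pax5, Cd72 and Spib are thus among those with a called neighbour. In chromosome order Cd72 and Pax5 stand side by side among these 10, so each may count only through the other. Coro2a, almost absent in ko, also differed between the wt replicates by 0.527 to 0.569 times in each population. A segment around Mzb1 and variants elsewhere therefore cannot be told apart from an effect of Mzb1, because too few genes are called and each group has 2 libraries.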

How the results depend on the processing

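Among the alternatives, those planned were fixed in advance; the pattern term, pattern A alone, equal totals, the fits without wt replicate 1 in all populations and those without small RNA genes were chosen after the data had been seen. Of 17566 combinations of a named gene, a comparison and an alternative, 16698 kept direction and side of the threshold, 800 fell below it, 66 rose above it and 2 reversed. For the lists these were 1505, 91, 58 and 2 of 1656. Unless a reason is given, the cause was not tested.

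In activated B cells 6 genes became 10 with no filter, 3 with the compared groups alone and 14 without wt replicate 1 in all populations, and 3 to 6 with 1 library left out. In pre-plasmablasts 13 became 20 with quantile normalization, 8 with the compared groups alone, 24 at equal totals and 7 to 8 with 1 library left out. In plasmablasts 45 became 27 with no filter, 8 with the compared groups alone, 10 to 41 with 1 library left out, 4 with the pattern term, 9 without wt replicate 1 in all populations, 72 at equal totals (60 higher, 12 lower) and 20 at a log2 change of at least 1. The compared groups alone leave fewer degrees of freedom, and the pattern term raised the SE.

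Between populations, 966 genes from wt pre-plasmablasts to plasmablasts became 532 with the compared groups alone, 1558 with the replicate block, 1461 with duplicateCorrelation, 248 to 418 with 1 library left out, 58 without wt replicate 1 in all populations and 1457 at equal totals (315 higher, 1142 lower). In ko, 1196 became 489 with the compared groups alone, 377 to 808 with 1 library left out and 724 without wt replicate 1. A minimum log2 change of 1, which removes genes by design, left 1801, 146 and 2456 genes in wt and 1778, 182 and 2422 in ko, for pre-plasmablasts against activated B cells, plasmablasts against pre-plasmablasts and plasmablasts against activated B cells. Equal totals moved the median of all genes to -0.24, -0.13 and -0.38 in these wt comparisons, from -0.021, 0.0092 and -0.014, and to 0.12 from 0.025 in ko against wt plasmablasts.

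Of the interactions, the 4 genes between pre-plasmablasts and activated B cells became 1 with the compared groups alone, 2 with a pseudocount of 0.1, 1 with pattern A alone and 1 to 4 with 1 library left out. The 0 between plasmablasts and pre-plasmablasts (limma; 272 at an unadjusted p below 0.05) became 4 with no filter, 1 with the pattern term and 0 to 1 with 1 library left out. The 5 between plasmablasts and activated B cells ranged from 2 to 10 with 1 library left out.

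Mzb1 stayed lower in ko under each alternative run, but in activated B cells its change of -1.72 missed the threshold with the compared groups alone (adjusted p = 0.0713; 1.98e-05 to 0.0713 over the alternatives). The 23 list calls between genotypes were 10, 4 and 9 by population, and 0 lists passed with an estimated correlation. With fry 0, 0 and 4 lists passed. In plasmablasts 7 of the 9 calls were lost with fry. Of its 4, 2 were lists that camera had not called, plasma cell identity, which includes Mzb1 itself, and marginal zone and B-1 markers. The replicate block gave 7 in pre-plasmablasts. In wt plasmablasts against activated B cells 0 of 12 passed with an estimated correlation. The likeness of the knockout changes rose from r = 0.40, 0.47 and 0.45 to 0.473, 0.521 and 0.515 with a mean of at least 5 FPKM and to 0.485, 0.559 and 0.584 with the pattern term, for pre-plasmablasts and activated B cells, plasmablasts and pre-plasmablasts, and plasmablasts and activated B cells.

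Reversals were few. Itgal in wt pre-plasmablasts against activated B cells went to -0.25 at equal totals, and Mzb1 in wt plasmablasts against pre-plasmablasts from 0.71 to -0.51 with quantile normalization. The test of the list cell cycle, ko vs wt in ActB, turned without ko replicate 2 (adjusted p from 2.74e-05 to 0.971 with 1 library left out), as did the translocon list in pre-plasmablasts with quantile normalization (0.951). Alternatives that need counts or immunoglobulin genes were not run, since the files hold FPKM and no constant-region genes: TMM, RLE, edgeR, DESeq2, voom and normalization without immunoglobulin genes. Depth limits could not be set, as absolute depth is unknown.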

Other observations

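The tests in this part, and the ribosomal protein set itself, were chosen after the results were seen. Ribosomal protein genes had a lower median in ko than in wt cells that had turned on Blimp1, though almost none was called singly. Over 78 of them the median log2 change of ko against wt was -0.07 in activated B cells, -0.35 in pre-plasmablasts, where 73 lay below 0, and -0.44 in plasmablasts, where 67 did. The unadjusted p of camera with an estimated correlation was 0.585, 0.0486 and 0.0364. limma called 0 of the genes lower in activated B cells, 0 in pre-plasmablasts and 1 in plasmablasts, Rpl6, at 55.0 FPKM in wt and 27.0 in ko. The nucleolar genes Fbl and Npm1 were also lower in ko plasmablasts, with log2 changes of -1.22 and -0.81 (adjusted p = 0.0246 and 0.0385); Npm1 was chosen after its values were seen. The call of Fbl was lost without each of the 4 plasmablast libraries in turn, with no filter and with a term for the fragment pattern. Against wt activated B cells the ribosomal median was -0.16 in wt pre-plasmablasts (95% limits -0.185 and -0.0934), where 56 lay below 0, and 0.05 in wt plasmablasts (-0.053 and 0.0994). These limits and those below come from resampling genes, which are not independent replicates, so they do not measure the spread between animals.

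A candidate explanation for the ribosomal pattern is reads shared with processed pseudogenes, but the 16 genes with at most 20% of their 50-mers in other genes had a median of -0.33 in plasmablasts (95% limits -0.461 and -0.266). The 61 with more shared 50-mers had -0.50 (-0.659 and -0.414), so a partial contribution stays open. An earlier form of this test, which used gene names, was replaced. Short transcripts are argued against, as 390 picks of other genes closest in length had a median of -0.034. The picks may repeat a gene and were not matched for level. The fragment pattern would leave the ko pre-plasmablast library of pattern A unchanged, yet its median against wt was -0.42. That is 1 library. In activated B cells the ko median against wt was 0.00616 for the library of pattern A and -0.146 for that of pattern B. In plasmablasts the pattern separates the genotypes fully, so its contribution there stays open. The direction held under quantile normalization (-0.36 in plasmablasts) and equal totals (-0.34), and an effect of Mzb1 and differences between the animals stay open.

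Some genes followed the replicate number, which the labels do not tie to an animal. Between the 2 wt replicates 20 genes, and between the 2 ko replicates 13, differed by at least 0.75 on the log2 scale in all 3 populations; the wt set holds Xist, the Y-linked genes, Coro2a, Slpi and Gdpd3, and the ko set holds Slpi and Gpx3. Gdpd3 stood at 0.189 and 0.168 FPKM in wt replicate 2 of activated B cells and plasmablasts and was listed at 0 in its pre-plasmablasts, against 14.9 to 91.7 in the other libraries. Leaving out wt replicate 1, the only wt libraries with Xist, in all 3 populations lowered the plasmablast count of 45. Leaving out either wt plasmablast library alone lowered it too. No fit left out wt replicate 2 in all 3 populations, so whether the loss relates to sex cannot be decided. These genes were chosen after their values were seen.

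Among the 3 wt populations, the mean of Apoe was highest in pre-plasmablasts, at 1497 FPKM against 85.1 in activated B cells and 111 in plasmablasts, and so was that of Ltb, at 69.5 against 20.9 and 4.78. Gapdh, a common reference gene and a member of the glycolysis list, was listed at 4.96 to 12.2 FPKM in the 12 libraries. In each population both ko libraries lay below both wt libraries. In plasmablasts they had 4.96 and 5.93 FPKM against 9.22 and 9.39 in wt. limma did not call Gapdh between genotypes in any population, and the cause of its low level was not tested.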
